A study of Mus musculus with 7 samples.

How the data were processed

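RNA from the medial amygdala of 7 Trap-Ai9 mice, 3 females and 4 males, was sequenced in bulk. Per the labels' protocols the tissue was cut as vibratome slices, the area was dissected under fluorescence and imaged to estimate the percent DIMPLE, and RNA was extracted with a column kit. Per the submitters' processing notes, cutadapt, TopHat2 2.2.1, HTSeq 2.0.1, DESeq2 1.26.0 and the mouse build GRCm39 were used, with no role, parameter, strand setting or annotation release given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies, such as the Y genes and their X relatives or the haemoglobin genes, may therefore be assigned uncertainly.

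The authors deposited 1 table for the series. It holds raw counts per gene and library, whole numbers with no normalization, per the file headers and values. It also holds a normalized signal, the counts divided by the authors' DESeq2 size factors, per the file headers. The authors' log2 fold changes (female over male), their standard errors, p-values and adjusted p-values stand in the same table, per the file headers. The deposited adjusted p equals a Benjamini-Hochberg adjustment over all deposited p-values, and genes with a fold change had a total count of at least 10. Coordinates are those of the table.

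Counts were analysed from the deposited raw values. Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested by edgeR 4.0.16 with a robust quasi-likelihood fit in R 4.3.3, with a Benjamini-Hochberg threshold of 0.05. Positive log2 fold changes mean higher in males. CPM are counts scaled to a common library size with TMM scaling, and n is the number of animals. The slope on percent DIMPLE was fitted with sex in the model, per 10 percentage points. Gene lists, 30 fixed before the data were examined, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) where at least 5 members were tested, with a preset inter-gene correlation of 0.01 and again with an estimated correlation. Lists share members, for example Slc17a7 and Fezf2 between the glutamatergic and cortical lists.

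The rule for named genes took all Y-linked list members and Xist, and, since none passed outside X and Y, the 5 genes of lowest p in each direction. Up to 4 members of lowest p were taken from each list, with Esr1, Pgr, Cyp19a1 and Fos in any case, and for the slope the 3 of lowest p in each direction. Some genes that the rule names are not reported here. Genes of the authors' table, members of a list that passed when adjusted over it, and genes in the closing section outside this rule were chosen after their values were seen.

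Total counts of 29049604 to 46494588 per library make counting error small for all but low genes, so that the spread between animals sets the precision. The chi-square over degrees of freedom between libraries was at least 31.1, so no pair was treated as a duplicate. On counts simulated from these libraries for the male over female comparison, with 200 of 20420 genes changed, edgeR recovered 17.7% of changes of 1 log2 unit and 67.3% of 2 log2 units, with 5.56% false calls. DESeq2 recovered 33.0% and 80.7% with 24.4% false calls. When the glutamatergic list was moved by 1 log2 unit, camera called it in 100% of 3 runs with either correlation, with 16.7% false among list calls at the preset correlation and 0% at the estimated one. The simulated genes varied independently, whereas the estimated correlation of this list in the data was 0.199. These runs therefore do not show how camera performs on correlated lists. Nor do they give the recovery or false calls of edgeR and DESeq2 where genes vary together. In the data, other splits of the libraries gave up to 78 (edgeR) and 474 (DESeq2) genes outside X and Y. For the DIMPLE slope, edgeR recovered 0.667% of slopes of 0.5 and 23.7% of slopes of 1 log2 unit per 10 points.

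Alternatives were other scalings, filters, DESeq2 1.42.0, limma-voom, percent DIMPLE or 1 surrogate variable (sva 3.50.0) as a covariate, the replicate number as a block, a threshold of 0.1, and leaving out each library. Added after seeing the data were DESeq2 on the genes the authors tested, comparisons by the column names of the male libraries, which the labels do not explain, a permutation of list means, DESeq2 without each library, camera on the slope without each library, and a slope for each sex.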

Results

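Bulk RNA-seq was made from the medial amygdala, a limbic nucleus that carries chemosensory and reproductive signals, of 3 female and 4 male mice sacrificed at 2 months of age. The animals were Trap-Ai9 mice (TRAP2-Ai9 in the series' design text), in which tamoxifen lets cells with active Fos be marked permanently by a red fluorescent reporter. Tissue containing the labelled area that the submitters call DIMPLE, a name the labels do not spell out, was dissected from slices of both hemispheres. Per the sample labels the females received tamoxifen at 6 weeks and the males at postnatal day 24, whereas the series' design text gives day 24 without setting the females apart. Sex therefore coincides with the age at tamoxifen. With sacrifice at 2 months in both groups, it also coincides with the interval from tamoxifen to sacrifice. Every difference below is a difference between these groups of animals. Total counts per library ranged from 29049604 in male replicate 1 to 46494588 in male replicate 3. The percent DIMPLE in the piece was 21.7 ± 2.89 (SD, n = 3) in females and 29.8 ± 9.11 (SD, n = 4) in males. These shares did not differ beyond their spread (two-sided exact permutation test, p = 0.2, smallest possible p 0.0286).

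The first comparison asked which genes differ between males and females. The 4 tested members of the Y-linked list and Xist, the RNA that silences an X chromosome, separated the sexes in every library. Of 10 genes tested on chromosome Y, these 4 passed the threshold. Ddx3y, an RNA helicase gene (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629, GRCm39), stood at 103 ± 22.9 CPM (SD, n = 4) in males and 0.144 ± 0.0664 CPM (SD, n = 3) in females. The histone demethylase gene Kdm5d stood at 17.1 ± 0.855 CPM in males and 0.220 ± 0.0381 CPM in females, and the translation factor gene Eif2s3y at 65.5 ± 21.5 and 0.0663 ± 0.0578 CPM. Xist (ENSMUSG00000086503, chromosome X, 102503972 to 102526860) stood at 54.2 ± 26.5 CPM in females and 0.183 ± 0.111 CPM in males. Uty was 28.9 ± 8.91 CPM in males and 1.6 ± 0.854 CPM in females, 5.54% of the male level, and its close relative Kdm6a on X may share reads with it. By edgeR's quasi-likelihood test the log2 fold changes, male over female, were 9.51 ± 0.36 (SE) for Ddx3y, 6.25 ± 0.26 for Kdm5d, 9.93 ± 0.56 for Eif2s3y, 4.15 ± 0.45 for Uty and -8.19 ± 0.54 for Xist. Their Benjamini-Hochberg adjusted p-values were 3.85e-06, 5.67e-06, 6.03e-05, 0.0141 and 0.000203. These were the 5 genes called among 20420 tested, 4 higher in males and 1 higher in females. The Uty call was lost without female replicate 3 (adjusted p = 0.138), without male replicate 1 (0.0522) or with 1 surrogate variable (0.0744). Leaving out male replicate 2 raised the count of called genes to 26.

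Outside the sex chromosomes no gene passed the edgeR threshold, and the genes described here, none of which passed, lay in both directions. Slc17a7, the vesicular glutamate transporter of cortical-type neurons (ENSMUSG00000070570, chromosome 7, 44813373 to 44825566), stood at 446 ± 266 CPM (SD, n = 4) in males and 64.5 ± 21.3 CPM (SD, n = 3) in females. The homeobox gene Emx1 stood at 5.05 ± 2.72 and 0.593 ± 0.0237 CPM, and the LIM homeobox gene Lhx9 at 19.5 ± 10.4 and 2.19 ± 0.814 CPM. Penk, which encodes the enkephalin precursor (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819), was 138 ± 25.8 CPM in males and 317 ± 21.6 CPM in females. Nmur2, a neuromedin U receptor gene, was 0.392 ± 0.224 and 4.72 ± 2.49 CPM.

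**Figure D1:**
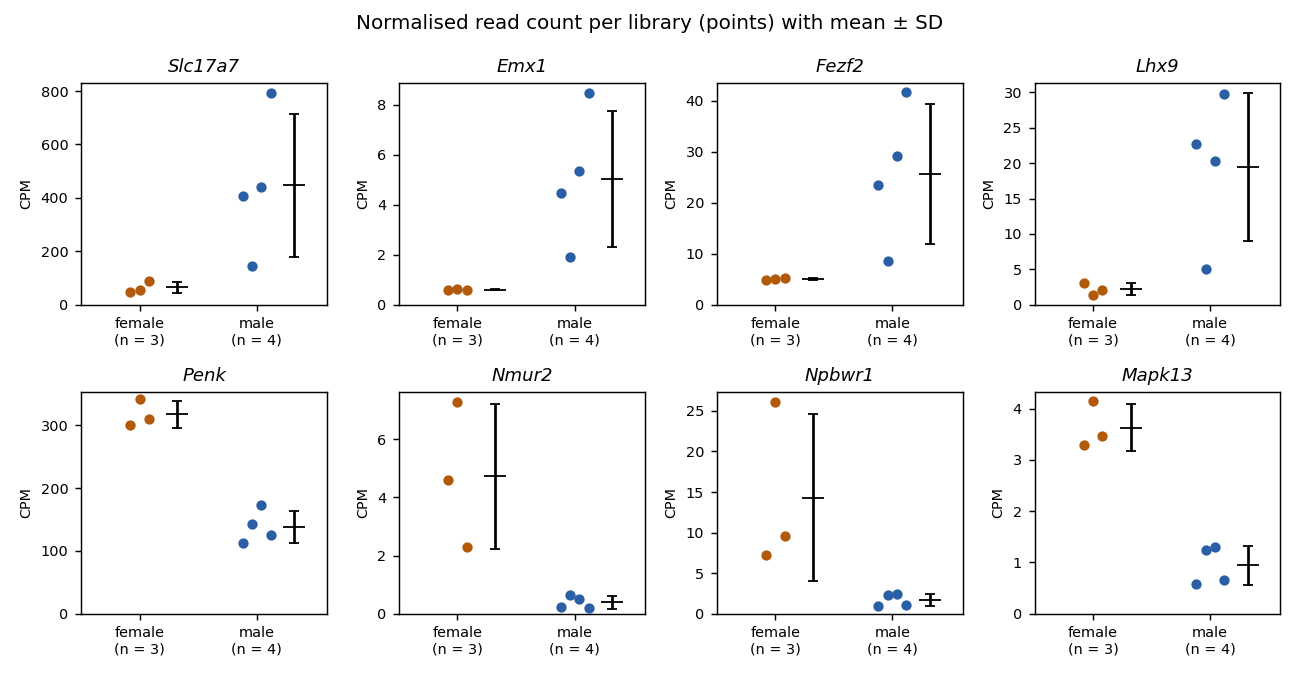
Normalised read count (CPM, linear axis from 0) of 8 genes, one point per library for 3 females and 4 males, with the mean and SD drawn beside the points. For Slc17a7, Emx1, Fezf2 and Lhx9 every male lies above every female, male replicate 2 being the lowest male, and for Penk, Nmur2, Npbwr1 and Mapk13 every male lies below every female.

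The log2 fold changes, male over female, were 3.93 ± 0.70 (SE) for Popdc3, 3.15 ± 0.56 for Lhx9, 3.09 ± 0.50 for Emx1, 2.80 ± 0.50 for Prdm8 and 2.38 ± 0.38 for Cabp7. In the other direction they were -3.56 ± 0.53 for Nmur2, -3.24 ± 0.61 for B3gnt7, -3.09 ± 0.51 for Npbwr1, -1.93 ± 0.36 for Mapk13 and -1.20 ± 0.18 for Penk. Adjusted p-values of these 10 genes ranged from 0.165 for Penk and Nmur2 to 0.363 for Mapk13 and B3gnt7 (edgeR). Of 19740 genes tested outside X and Y, edgeR called 0 and limma-voom 0. DESeq2, with its own gene filter, called 115 outside X and Y, 88 higher in males and 27 higher in females. This DESeq2 count was 51 without male replicate 4 and 306 without male replicate 2. At an unadjusted p under 0.05 edgeR gave 907, 524 higher in males and 383 higher in females. Over all 20420 genes it gave 962, against 1021 expected by chance. The 907 became 349 with percent DIMPLE in the model and 1573 with 1 surrogate variable. The groups did not overlap for 5.22% of all 19740 genes, against 5.71% expected by chance. Without male replicate 2 edgeR called 20 genes outside X and Y, among them Lhx9 (adjusted p = 0.0112), Emx1 and Prdm8 (0.0159 each), Slc17a7 (0.0169), Cabp7 (0.0313) and Popdc3 (0.0391), and without female replicate 1 it called 1, B3gnt7 (adjusted p = 0.00141). Male replicate 2 had the lowest percent DIMPLE (18), and without it every male (29 to 40) lay above every female (20 to 25). Sex and percent DIMPLE then cannot be told apart, here and wherever male replicate 2 is left out.

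The authors' deposited table marks 143 genes at an adjusted p under 0.1, 105 higher in males and 38 higher in females, of which 134 lie outside X and Y. In the authors' deposited table the adjusted p was 9.15e-09 for Popdc3, 7.13e-08 for Emx1, 1.36e-06 for Slc17a7, 9.15e-09 for Nmur2 and 0.000114 for Penk. Of the 141 genes marked in the authors' deposited table that were also tested by edgeR, 141 had the same direction and an unadjusted p under 0.05 there. Both fits use the same counts and contrast, and the genes were marked for a low p, so this match is not independent evidence. The authors' deposited table also places Bves, which lies next to Popdc3 on chromosome 10, higher in males (log2 fold change 3.16, adjusted p = 2.24e-05).

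Gene lists fixed before the data were examined described the tissue by cell type. Among 17 glutamatergic neuron genes, 13 had a higher and 4 a lower estimate in males, with a median log2 fold change of 1.64. No member passed over all genes tested, while 7 rose and 1 fell when adjusted over the list alone. The 7 included Emx1, Slc17a7, the projection neuron factor Fezf2 (25.7 ± 13.7 CPM in males, 5.07 ± 0.207 in females) and Neurod2 (30.7 ± 18.4 and 5.64 ± 1.08 CPM), each of which also passed in all 18 alternative edgeR settings. Over all genes Fezf2 (adjusted p = 0.0129) and Neurod2 (0.0159) passed without male replicate 2, as did Emx1 and Slc17a7. The count that rose was 11 without male replicate 3 or without a low-count filter. Neurod1 and Nrn1, also among the 7, lost the call with percent DIMPLE in the model (adjusted p over the list = 0.0731 each). The member that fell was Otp (2.47 ± 1.33 and 6.55 ± 2.46 CPM), a call lost without female replicate 1 (adjusted p = 0.0563), female replicate 3 (0.0937) or male replicate 4 (0.0661) and with percent DIMPLE in the model (0.0970). The list median was 0.98 without male replicate 1 and 0.81 with percent DIMPLE in the model. The list ranked above other genes with camera's preset correlation (adjusted p = 1.37e-06), a call lost with an estimated correlation (adjusted p = 0.456 with an estimated correlation). Of 20 cortical and basolateral amygdala projection neuron genes, 0 passed over all genes and 5 rose when adjusted over the list alone, among them Nptx1 (286 ± 138 CPM in males, 95.5 ± 16.4 in females) and Crym (159 ± 95.9 and 40.2 ± 14.7 CPM). The 5 became 3 without female replicate 2, 2 without female replicate 3 and 11 without male replicate 2, and 0 with percent DIMPLE in the model. In that last model their log2 fold changes were 2.33 for Slc17a7, 1.80 for Fezf2, 1.38 for Nptx1, 1.29 for Slc30a3 and 1.23 for Crym. Nptx1 lost its call without female replicate 3 (adjusted p = 0.0557), and Crym without female replicate 2 (0.0851) or 3 (0.0594). Against the males whose columns begin with mv both lost it (0.0547 each), Nptx1 at a log2 fold change of 0.82 against 1.58. Crym also lost it without a low-count filter (0.0720) or with 1 surrogate variable (0.0814). The cortical list's camera adjusted p was 0.000129, and 0.456 as an adjusted p with an estimated correlation.

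Peptide and inhibitory neuron lists had lower medians in males. Of 27 neuropeptide genes 20 had lower estimates in males (median log2 fold change -0.51, and -0.22 without female replicate 3). Penk fell when adjusted over the list alone, as it did in all 18 alternative edgeR settings, and 0 passed over all genes. The number of neuropeptide genes that fell, 1 here, was 3 without female replicate 2, 4 without male replicate 2, 2 without male replicate 4, 4 without a low-count filter and 8 with 1 surrogate variable or against the males whose columns begin with mb. Pdyn, the dynorphin precursor gene, stood at 40.5 ± 11.8 CPM in males and 68.3 ± 11.8 in females, and Pnoc, the nociceptin precursor gene, at 75.5 ± 17.5 and 112 ± 3.25 CPM. The camera adjusted p-values were 2.52e-05 for neuropeptides, 0.00294 for GABAergic neurons, 8.19e-08 for hypothalamic neurons, 0.0120 for striatal projection neurons and 0.00109 for imprinted genes. Each of these 5 had an adjusted p = 0.456 with an estimated correlation. With percent DIMPLE in the model the GABAergic and striatal calls were lost, and against those with mv the neuropeptide, GABAergic and imprinted calls. Adjusted over the list alone, 0 of 18 GABAergic and 0 of 21 hypothalamic genes passed. Without male replicate 2 the GABAergic list had 6 that fell and 1 that rose, and the hypothalamic list 11 that fell. Against the males whose columns begin with mb the GABAergic list had 8 that fell and 1 that rose and the hypothalamic list 7 that fell, and with the column name as a term 5 hypothalamic genes fell and 1 rose. The hypothalamic list also had 4 that fell without female replicate 2, 1 without female replicate 1, 6 without a low-count filter and 5 with a replicate block. In the striatal list Penk fell and Bcl11b rose, and among imprinted genes Dio3 rose (15.3 ± 8.10 CPM in males, 3.14 ± 0.776 in females), adjusted over the list alone. With percent DIMPLE in the model Bcl11b (adjusted p = 0.0844) and Dio3 (0.269) lost these calls, and Dio3 also without female replicate 1 (0.0894), female replicate 2 (0.0928) or male replicate 4 (0.0535). Without male replicate 2 Dio3 passed over all genes (adjusted p = 0.0313), and 7 imprinted genes fell adjusted over the list alone, as 3 did without female replicate 3. The striatal call of camera was lost without female replicate 2 (adjusted p = 0.147), male replicate 1 (0.105) or male replicate 2 (0.0533). The hypothalamic list was highest in female replicate 3, 1.6 log2 units above its mean over the libraries.

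No gene of sex steroid signalling passed the test. Esr1, the estrogen receptor alpha gene, stood at 48.6 ± 6.83 CPM in males and 73.4 ± 33.1 in females, Pgr at 38.1 ± 6.63 and 40.1 ± 9.84, and the aromatase gene Cyp19a1 at 23.9 ± 7.31 and 26.3 ± 6.08. No gene of the steroid receptor and synthesis list passed over all genes or adjusted over the list alone (camera adjusted p = 0.330), though 1 rose adjusted over the list alone without female replicate 3 or without a low-count filter. In the list of sex- or hormone-dependent limbic genes Brs3 fell when adjusted over the list alone (21.7 ± 11.7 CPM in males, 69.1 ± 18.7 in females). Brs3 lost this call without female replicate 1 (adjusted p = 0.0840), 2 (0.187) or 3 (0.0642), without male replicate 1 (0.0627) or 3 (0.0822), and with percent DIMPLE in the model (0.298). The Brs3 log2 fold change was -1.50 with percent DIMPLE in the model and -1.67 without it. That list's camera adjusted p was 0.00691, and 0.556 as an adjusted p with an estimated correlation. The list's call was lost without female replicate 2 (adjusted p = 0.311), male replicate 3 (0.0625) or male replicate 4 (0.103), and with percent DIMPLE in the model. Of 13 X-inactivation and escape genes, Xist fell over all genes and 2, Xist and Eif2s3x (65.6 ± 2.10 CPM in males, 95.2 ± 12 in females), fell when adjusted over the list alone. Eif2s3x lost this call without female replicate 1 (adjusted p = 0.0615) or 2 (0.0968), without male replicate 1 (0.0580), 2 (0.0934), 3 (0.0727) or 4 (0.0847), and with percent DIMPLE in the model (0.105) or a replicate block (0.152). The X list's camera adjusted p, with Xist among its members, was 0.000428, and 0.259 as an adjusted p with an estimated correlation.

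Receptor and developmental lists held members of both directions without a camera call, except that the receptor list ranked lower in males without female replicate 3 (camera adjusted p = 0.0360). Among 35 neuropeptide and hormone receptor genes, 2 rose and 4 fell adjusted over the list alone. None passed without female replicate 1, without female replicate 3 or with percent DIMPLE in the model, while 1 rose and 0 fell without female replicate 2 or male replicate 3. Without male replicate 1, 2 rose and 1 fell, without male replicate 2, 4 rose and 6 fell, and without male replicate 4, 1 rose and 1 fell. Oxtr, the oxytocin receptor gene, stood at 34.8 ± 10.6 CPM in males and 16.7 ± 1.79 in females, and Avpr1a, a vasopressin receptor gene, at 2.43 ± 1.71 and 7.25 ± 0.876. Without male replicate 2 Avpr1a (adjusted p = 0.0313) and Prokr2 (0.0248) passed over all genes. Lhx9 and Zic2 rose in the amygdala lineage list, and Prokr2, Igfbpl1 and Neurod1 in the immature neuron list, again adjusted over the list alone and with 0 passing over all genes. Lhx9 kept this call in all 18 alternative edgeR settings. Zic2 lost it without female replicate 1 (adjusted p = 0.0756), 2 (0.0859) or 3 (0.0968), without male replicate 1 (0.0958) or 4 (0.137), and with percent DIMPLE in the model (0.334). Prokr2 (0.0851), Igfbpl1 (0.117) and Neurod1 (0.231) lost it with percent DIMPLE in the model. The log2 fold changes of these genes were then 2.00, 1.94 and 1.36, against 2.33, 2.29 and 1.87 without percent DIMPLE. Without female replicate 1 Igfbpl1 (adjusted p = 0.0502) and Neurod1 (0.0712) lost the call, and Neurod1 also without female replicate 2 (0.0782). The immature neuron list had a median log2 fold change of -0.09, a mean of 0.25 and a camera direction of lower in males. Thalamic and habenular genes had a median of 0.17 and a mean of 0.05 with the camera direction lower in males. Fos stood at 13.3 ± 13.0 CPM in males and 9.32 ± 4.92 in females, and the immediate early list was not called (camera adjusted p = 0.0994), but was without female replicate 3 (0.0432), male replicate 1 (0.0416) or male replicate 2 (0.00367).

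Oligodendrocyte lineage, endothelial, matrix and mitochondrial lists were higher in males by camera, with 0 members of each passing over all genes or adjusted over the list alone. With an estimated correlation the adjusted p was 0.456 for the myelin, 0.545 for the precursor, endothelial and matrix, and 0.600 for the mitochondrial list. Adjusted over the list alone, 1 matrix gene rose without female replicate 2 or male replicate 2. In the same way 14 of 23 myelin, 4 of 15 precursor and 3 of 13 mitochondrially encoded genes rose with 1 surrogate variable, 12 myelin genes with a replicate block, 19 myelin genes against the males whose columns begin with mb and 6 mitochondrially encoded genes against those with mv. The median log2 fold changes were 0.78 for 23 myelin genes (adjusted p = 9.07e-09), 0.34 for 15 oligodendrocyte precursor genes (0.000717), and 0.44 for 13 mitochondrially encoded genes (0.00411). The adjusted p-values were 0.00230 for 17 endothelial and 0.0163 for 18 perineuronal net and matrix genes. Without male replicate 3 the medians were 0.36 for myelin and 0.19 for precursor genes, and without male replicate 2 the precursor median was 0.21. Against the mv males they were 0.26 and 0.15, and the precursor list lost its call. Male replicate 3 lay 1.13 log2 units above the mean of the libraries for myelin genes, and male replicate 1 lay 1.09 above it for mitochondrially encoded genes. In male replicate 1 mitochondrially encoded genes took 5.74% of counts (95% Wilson interval 5.73 to 5.75, counting error only), against 2.24% to 2.88% in the other libraries. Without male replicate 1 the mitochondrial list had a median of 0.04 and lost its call (adjusted p = 0.498), as it did without female replicate 2 (0.0668). The endothelial call was lost without male replicate 3 (adjusted p = 0.121) or female replicate 2 (0.355). With percent DIMPLE in the model the endothelial and mitochondrial calls were lost. The perineuronal net call was lost without male replicate 3 (adjusted p = 0.176), male replicate 2 (0.0632), female replicate 1 (0.0914) or female replicate 3 (0.223).

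**Figure D2:**
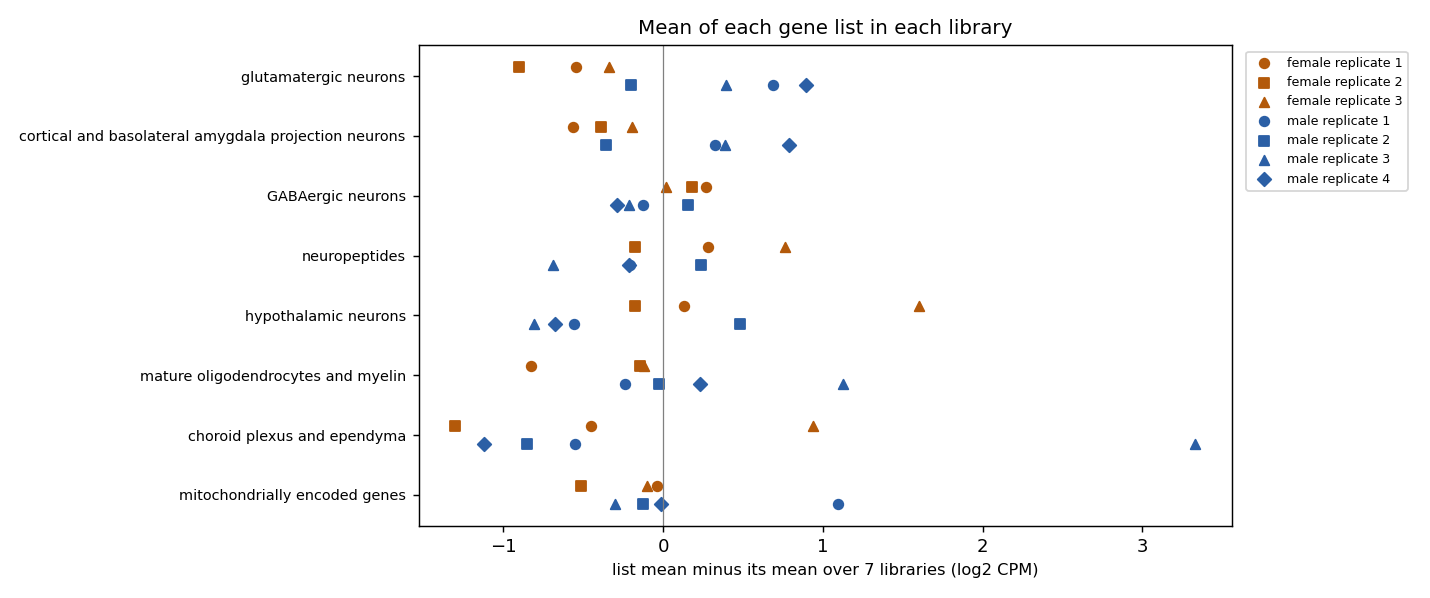
Mean log2 CPM of 8 gene lists in each of 7 libraries, drawn relative to the list's mean over the libraries, with females and males in different colours and one symbol per replicate. Glutamatergic neuron genes lie between -0.90 and -0.34 in females and between -0.20 and 0.90 in males, and male replicate 3 stands alone at 3.33 for choroid plexus and ependyma genes.

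The lists left without a camera call had medians, male over female, of 0.09 for sex steroid genes, -0.08 for receptors of neuropeptides and hormones, -0.16 for amygdala lineage factors, 0.05 for proliferating cells, 0.27 for immediate early genes, 0.10 for heat shock genes, 0.02 for astrocytes, 0.05 for microglia, 0.40 for pericytes, 2.57 for choroid plexus and ependyma, 0.20 for blood, -0.05 for GABA and glutamate receptors and -0.03 for interferon response genes. Leaving out 1 library made camera call some of them. Pericyte genes were higher in males without female replicate 1 (adjusted p = 0.0326), female replicate 3 (0.0213), male replicate 1 (0.00488) or male replicate 2 (0.0161), and astrocyte (0.0252) and proliferating cell genes (0.0346) without female replicate 2. GABA and glutamate receptor genes were lower in males without female replicate 3 (0.00599), and choroid plexus genes without male replicate 3 (0.0345). Of 29 lists tested, camera called 14 with the preset correlation, 7 in each direction, and 0 with an estimated correlation. In an exact permutation test of list means only the X-inactivation and escape list reached the smallest possible p of 0.0286. Its mean includes Xist (log2 fold change -8.19), while its median was -0.25, and it was not tested without Xist. Adjusted over 29 lists a test with this floor could hardly have called any. The 4 tested members of the Y-linked list, out of 10 genes tested on chromosome Y, were too few for the list test. Of these members 4 of 4 rose, over all genes and adjusted over the list alone.

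The second comparison asked whether expression followed the percent DIMPLE of the piece, with sex in the model. Cd24a, a surface glycoprotein gene of immature neurons, had a slope of 0.95 ± 0.23 (SE) log2 units per 10 percentage points, C1galt1c1 0.69 ± 0.17 and Pno1 0.55 ± 0.13. Lhx6, a transcription factor gene of inhibitory neurons, had a slope of -0.63 ± 0.18 and Spint1 -0.56 ± 0.16. None passed, with an adjusted p of 0.897 for each of these 5 (edgeR, n = 7 libraries). Of 20420 genes edgeR called 0, with 928 at an unadjusted p under 0.05 against 1021 expected by chance. That number was 504 without male replicate 1, 1477 without male replicate 2, 1692 without male replicate 3 and 2120 with no sex term, so it lies on either side of chance. DESeq2 and limma-voom also called 0, with 1035 and 722 at an unadjusted p under 0.05. Camera ranked mitochondrially encoded (adjusted p = 0.000169) and glutamatergic genes (0.0251) toward positive slopes and oligodendrocyte precursor (0.00305) and astrocyte genes (0.00483) toward negative slopes, each with adjusted p = 0.684 with an estimated correlation. Hypothalamic neuron, limbic and receptor lists also ranked toward negative slopes (adjusted p = 0.00615, 0.00615 and 0.0251), again with adjusted p = 0.684 with an estimated correlation. Each of these 7 list calls was lost without 1 library or another. Without male replicate 1, which had both the highest percent DIMPLE and the 5.74% of mitochondrially encoded counts, the mitochondrial (adjusted p = 0.429), precursor (0.682) and receptor (0.601) calls were lost. Without male replicate 2 the glutamatergic (0.369), hypothalamic (0.636), limbic (0.288) and astrocyte (0.0509) calls were lost. The glutamatergic call was also lost without female replicate 2 (0.0563) or male replicate 3 (0.0833), and the receptor call without female replicate 2 (0.0566).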

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

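Except for the counts over other splits of the libraries, of which that for Y-linked genes and Xist was added later, the tests in this part were chosen after the results were seen. In the group of 4 males, 167 values were checked for 1 library far from the others and 11 stood out, where chance alone gives about 1 in 20.

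Male replicate 3 carried choroid plexus transcripts. The list mean was 6.86 log2 CPM there against 2.41 to 2.98 in the other males and 2.23 to 4.47 in females. Ttr stood at 13.73 log2 CPM, Enpp2 at 12.77 and Kl at 9.0. Counting noise is argued against by 627180 counts of Ttr, while 10 of 15 list members were highest in this library, which is consistent with choroid plexus tissue in that piece. The ependymal genes Ccdc153, Tmem212 and Dnah11, and also Rarres2 and Prlr, were highest elsewhere. Foxj1, another ependymal gene, was highest in male replicate 3 (52.9 CPM, against 40.9 in female replicate 3). No biological explanation was tested.

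Cldn11 (5.37) and Igf2 (3.54 log2 CPM) were also highest in male replicate 3. Male replicate 1 had the lowest receptor list mean (3.59) of the males, their lowest C1ql1 (4.85) and Has2 (-0.85, from 14 counts), and their highest Ddx3y (7.10). Male replicate 4 had the lowest Xist (-3.74), at 1 count against 6, 8 and 13 in the other males, where counting error is large.

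The higher median of the glutamatergic neuron list in males, with 13 members higher and 4 lower, was weighed against 3 technical explanations. Dependence on 1 library is argued against, since the lowest median log2 fold change without a library was 0.98 (without male replicate 1). Camera with the preset correlation kept the call in each case, though it was lost with an estimated correlation (adjusted p = 0.456). With the preset correlation other splits of the libraries called 1 to 16 of 29 lists, so keeping the call adds little. With percent DIMPLE in the model the sex coefficient of the list mean went from 1.04 ± 0.31 (SE) to 0.74 ± 0.31, within 1 SE of 0.52, so the share of DIMPLE cannot be told apart with 7 libraries. Uneven capture of neighbouring pallial tissue may contribute: the spread of the list mean within a sex (SD 0.41) lay at percentile 100 of 10000 random lists matched on expression, though co-expressed genes would also spread widely. Sex, the age at tamoxifen and the interval from tamoxifen to sacrifice remain open, untested and inseparable.

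Chance is an unlikely source of the calls of the Y-linked list members and Xist, with folds of 17.8 (Uty) to 974 (Eif2s3y) and no overlap between the sexes. Of 35 splits of the libraries 1, the real one, called the 4 tested list members and Xist, and the other splits called 0 of these 5. Any other split mixes males and females, so this count checks the labels and adds little about chance. The number of genes called is another matter. For edgeR, 3 of the 35 splits of the libraries into 3 and 4 gave at least the 5 genes of the real split, the highest other 83, so chance cannot be excluded for the count. For genes outside X and Y the real count was 0, which 35 of 35 splits reach by necessity (highest other 78), so they decide nothing there. For DESeq2, 8 of 35 splits gave at least the 115 genes of the real split, the highest other 474, and chance cannot be excluded. For camera with the preset correlation, 4 of 35 gave at least 14 lists, the highest other 16, and chance cannot be excluded. The split with 83 and 474 genes, picked as the highest of 35, sets male replicates 1, 3 and 4 against the females and male replicate 2. For DESeq2 the split of female replicate 2 and male replicates 2 and 3 against the rest gave 459, but 0 by edgeR. Whether the 83 and 474 reflect a structure of the samples was not tested. The split with 83 and 474 genes is also the split by percent DIMPLE, 29 or more against 25 or less. Percent DIMPLE stays open as its origin. The slope without a sex term called 0 genes, with 2120 at an unadjusted p under 0.05 against 1021 expected by chance. With sex in the model edgeR recovered 23.7% of simulated slopes of 1 log2 unit, so a count of 0 decides little.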

How the results depend on the processing

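The DESeq2 run on the authors' genes, comparisons by column name, the permutation of list means and DESeq2 and the slope lists without each library were chosen after seeing the data. The 5 genes called became 12 without a low-count filter, 122 with DESeq2, 105 with DESeq2 on the authors' genes and 48 for females against the males whose columns begin with mb. Leaving out a library gave 4 to 26. Outside X and Y the count of 0 became 6 without a filter, 3 with 1 surrogate variable, 115 with DESeq2, 96 with DESeq2 on the authors' genes, 41 against the mb males and 1 with the column name as a term, and 0 to 20 without a library. The DESeq2 count outside X and Y ranged from 51 (without male replicate 4) to 306 (without male replicate 2). The count of 14 lists became 9 against the mv males, and 0 with an estimated correlation. By permutation it was 0, which 35 splits all but fix. Of the 14 called lists, 9 kept their call without each library in turn. The choroid plexus list turned from 2.57 to -0.55 without male replicate 3, the library that carried it, the highest value being 3.69 without female replicate 3. For the DIMPLE slope the count of 0 became 15 without a filter. Camera's direction along the slope turned for mitochondrial genes without male replicate 1 (median 0.0219), and without male replicate 2 for glutamatergic (-0.305), hypothalamic (-0.000921) and limbic genes (0.109). The farthest medians were 0.936, -0.667 and -0.409 for these lists without male replicate 1, and 1.012 for mitochondrial genes without male replicate 2. Apart from the choroid list the cause was not tested.

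With a replicate block the counts were 27 genes, 20 outside X and Y, 16 lists and 9 for the slope, the last with 1 residual degree of freedom. Male replicate 4 stood alone in its block, so it added nothing to the sex contrast of this fit. Replicate numbers name different animals, so they do not pair the samples by animal. Same-numbered deviations correlated at 0.31, 0.17 and 0.03, and of the females only replicate 1 matched its own number best. These values cannot decide whether a number marks a shared batch. Of 2586 alternative values of named genes, 2488 stayed on the same side of the threshold, 95 newly passed and 3 (Uty) no longer passed. In 0 did the direction turn with a call in either fit. Turns of direction where neither fit passed were not counted apart and lie among the 2488.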

Other observations

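These tests were chosen after the data were seen. Gene ontology terms given in the authors' deposited table were tested among the genes it marks outside X and Y. Of 4054 terms, 7 were enriched among genes higher in males and 0 among those higher in females. Telencephalon development held 4 of 27 term genes, Emx1, Fezf2, Lhx2 and Oxtr (adjusted p = 0.0260), and neuron differentiation 7 of 160, among them Lhx9, Neurod1, Neurod2 and Nr4a2 (adjusted p = 0.0260). Response to hypoxia (7 of 180, among them Dio3 and Nr4a2) and growth factor activity (6 of 124, among them Bdnf and Fgf5) had the same adjusted p. These genes come from DESeq2 calls whose number other splits of the libraries also reached, and genes that vary together are not independent.

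The male columns carry 2 name stems that the labels do not explain. Between these pairs of males edgeR called 0 of 20420 genes, with 1180 at an unadjusted p under 0.05 and a smallest adjusted p of 0.489. The lowest p belonged to Scgn, a calcium-binding protein gene, at 24.2 and 28.8 CPM in male replicates 1 and 2 and 8.08 and 7.21 CPM in male replicates 3 and 4. Gal, the galanin gene, stood at 41.9 and 57.4 CPM in male replicates 1 and 2 and 12.9 and 12.3 CPM in male replicates 3 and 4. The haemoglobin genes Hba-a2 (27.9 and 38.7 against 11.9 and 11.7 CPM) and Hbb-bs (72.8 and 84.0 against 33.3 and 31.7 CPM) came next. Adjusted over the blood list alone, 4 genes rose over the females in male replicates 1 and 2, and 3 fell in male replicates 3 and 4.

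For a difference between the sexes in the slope on percent DIMPLE edgeR called 0 of 20420 genes. The female slope rests on female replicate 1 alone (25 against 20 and 20 percent), so this decides nothing about whether the slopes differ.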
